A study of Arabidopsis thaliana with 24 samples.

How the data were processed

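Steady-state RNA was measured in 24 libraries from 2 tissues and 4 genotypes of Arabidopsis thaliana, 3 per group. Per the labels' protocols, 500 ng of DNase-treated total RNA per library was depleted of ribosomal RNA, made into strand-specific paired libraries and sequenced to reads of 50 bases. Groups and replicate numbers were taken from the labels, which call the replicates biological.

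The authors deposited 1 table per tissue of raw read counts per gene, not normalized, with 12 libraries each. Per the file headers, featureCounts 2.0.6 counted reads over the whole span of a gene, introns included, in reverse-stranded paired mode, and a read overlapping several genes was counted for each. The recorded command is incomplete, so whether reads or read pairs were counted is not given in the sources used here. Per the submitters' processing notes, bcl2fastq, HISAT2 2.2.1, featureCounts 2.0.6, R 4.2.2, DESeq2 1.38.3 and TAIR10 were used. Whole-span counting takes in RNA from introns and from transcripts that start inside a gene, and 1918 genes overlap another gene on the same strand. Of 33243 gene IDs, 33056 were found in the reference annotation, 33055 of them with the same start and end, and the 187 organellar IDs without a match kept their deposited names. Of counts from 1 to 20, 66.7% to 77.2% were even per library, so a run with halved counts was added after this was seen.

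Total counts per library ranged from 19304121 to 38853305 in seeds and from 23787015 to 39797391 in flowers. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom from 17.0 to 266, so each library was counted as its own replicate. Plastid genes held 5.49% to 9.38% of counts in seeds and 20.85% to 26.86% in flowers.

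Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and minimum total of 15, TMM normalization, robust quasi-likelihood fit, prior count 0.125), with one mean per group over the 12 libraries of a tissue, or over all 24 for the difference between tissues. The filter left 17939 genes in seeds, 22841 in flowers and 23557 in the joint fit, and the threshold was an adjusted p of 0.05 by Benjamini-Hochberg. The biological coefficient of variation was 0.18 in seeds and 0.268 in flowers. CPM were computed here with TMM-scaled library sizes. Each mutant was compared with WT, the double mutant with each single mutant, and the departure from additivity of both insertions was tested. Shared controls were simulated with 20 unchanged data sets. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

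The genes named were chosen by a rule. URT1 and HESO1 are always given. Up to 6 genes with the largest rise and 6 with the largest fall are given per comparison with WT, among those past the threshold whose 3 mutant libraries all lay beyond all 3 WT libraries and whose higher group mean reached 1 CPM. For the other comparisons up to 3 per direction are given without the no-overlap condition. Up to 4 members per described list are given, by smallest adjusted p, and 3 annotated genes on each side of URT1 and HESO1 were examined. Genes outside the rule are named as chosen after their values were seen.

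The 22 gene lists were the mRNA decay machinery, small RNA machinery, miRNA and tasiRNA targets, siRNA-prone mRNAs, seed storage and oil body proteins, late embryogenesis abundant and abscisic acid-responsive genes, seed maturation regulators and fatty acid synthesis, dormancy and germination control, heat shock proteins, floral organ identity, tapetum and early anther, mature pollen, photosynthesis, seed coat, endosperm, salicylic acid and defence, jasmonate, short-lived stress-responsive mRNAs, cell division, plastid-encoded, mitochondrion-encoded and cytosolic ribosomal proteins. They were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with other genes, and fry tests whether its members move one way on balance. A wider ribosomal protein list was added after the data were seen.

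Replicate numbers come from the labels, which do not say what a number stands for. Pairing was judged by whether the deviations of same-numbered libraries from their group means correlated above 0.1 in every pair. They did for urt1-1 and WT in seeds (0.40, 0.20 and 0.51) and flowers (0.60, 0.13 and 0.44), for libraries labelled heso1-4 and WT in flowers (0.55, 0.22 and 0.45), and for libraries labelled heso1-4 urt1-1 against urt1-1 in seeds (0.11, 0.21 and 0.19) and flowers (0.69, 0.38 and 0.62) and against libraries labelled heso1-4 in seeds (0.12, 0.16 and 0.18) and flowers (0.63, 0.35 and 0.42). For these the result with the replicate number as a block is given where it changes a call or moves a count by over 1.5 times. The block was a common effect of each replicate number over all 12 libraries of a tissue. That fit also holds pairs of groups that did not meet the criterion, so it is not a paired test of 2 groups alone.

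The test was tried on simulated data with 50 genes changed at each fold. For urt1-1 against WT in seeds (17634 genes) it recovered 38%, 66%, 98% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, with 3.1% of calls false. For the same comparison in flowers (22473 genes) it recovered 10%, 46%, 88% and 92%, with 3.3% of calls false. The changed genes were drawn from those at 1 CPM or more, and many more changed than were called in the real data. This loosens the cut-off that the adjustment sets. Libraries were drawn independently, without the shared deviations of same-numbered libraries. The shares recovered may therefore be higher than in the real comparisons.

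Groups, comparisons, lists, the rule for named genes and these alternatives were fixed before the data were examined: DESeq2 1.42.0 (Wald test), DESeq2 size factors within edgeR, no filter on low counts, a stricter filter of 1 CPM in 3 libraries, nuclear genes only, only the 2 groups compared, separate tissue fits, the replicate block, leaving out each library, and a log2 fold change of at least 1. Chosen after seeing the data were halved counts, the fit without the third seed library labelled heso1-4, flower replicates 2 and 3 only, and the wider list. Levels of seeds and flowers were not compared with each other, because RNA extraction differed between them.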

Results

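Steady-state RNA was measured in dry mature seeds and in unopened flower buds of Arabidopsis thaliana Col-0 (WT) and of plants carrying T-DNA insertions in the terminal uridylyltransferase genes URT1 (urt1-1), HESO1 (heso1-4) or both (heso1-4 urt1-1). URT1 adds uridines to the 3′ ends of messenger RNAs and HESO1 is known for uridylating small RNAs. By their labels the comparisons concern loss of either or both enzymes. HESO1 RNA was higher, not lower, in libraries labelled heso1-4 or heso1-4 urt1-1, so loss of HESO1 was not shown. The 24 libraries form 8 groups of 3, which the labels call biological replicates, each from tissue pooled from at least 5 plants. Seeds were collected 8 weeks and flower buds 2 weeks after flowering onset, and RNA of the 2 tissues was extracted by different methods, so tissue and extraction cannot be told apart. In seeds, the total counts on genes for replicates 1, 2 and 3 were 19304121, 30204916 and 25625320 in WT, 24351440, 37944609 and 38706435 in urt1-1, 26661427, 21105548 and 32245131 in libraries labelled heso1-4, and 32791298, 37592790 and 38853305 in libraries labelled heso1-4 urt1-1. In flowers they were 34537256, 27790775 and 33964498 in WT, 31536006, 23787015 and 31186047 in urt1-1, 24999000, 33977098 and 39797391 in libraries labelled heso1-4, and 24177931, 30659070 and 35121859 in libraries labelled heso1-4 urt1-1. Positions are those of the deposited tables on the TAIR10 assembly. Group values are mean CPM (counts scaled to a common library size) ± SD over 3 libraries, fold changes are log2 ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another source is named. For each gene named as called between 2 groups over all genes tested without a block, 3 of 3 libraries of the first group lay beyond all 3 libraries of the other.

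URT1 (AT2G45620, protein-coding, chromosome 2, 18792864 to 18795904) RNA was nearly lost in both groups labelled as carrying urt1-1. In seeds it stood at 108 ± 3.06 CPM (SD, n = 3) in WT, 2.63 ± 0.211 in urt1-1, 97.5 ± 9.52 in libraries labelled heso1-4 and 3.62 ± 0.189 in libraries labelled heso1-4 urt1-1. The fall against WT was −5.35 ± 0.12 in urt1-1 (edgeR adjusted p = 3.8e-13) and −4.89 ± 0.11 in libraries labelled heso1-4 urt1-1 (8.7e-13). In flowers URT1 stood at 47.2 ± 5.79, 2.41 ± 0.468, 47.8 ± 1.19 and 2.49 ± 0.186 CPM in the same order, a fall of −4.29 ± 0.16 (3.3e-07) in urt1-1 and −4.24 ± 0.16 (3.5e-07) in libraries labelled heso1-4 urt1-1. HESO1 (AT2G39740, protein-coding, chromosome 2, 16575752 to 16579120) went against its label. Its count was higher, not lower, in every library labelled heso1-4 or heso1-4 urt1-1 than in any WT library. In seeds HESO1 stood at 0.452 ± 0.115 CPM (SD, n = 3) in WT, 0.244 ± 0.153 in urt1-1, 182 ± 5.21 in libraries labelled heso1-4 (log2 fold change 8.60 ± 0.21, edgeR adjusted p = 1.4e-12) and 49.1 ± 2.59 in libraries labelled heso1-4 urt1-1 (6.71 ± 0.20, 2.0e-11). In flowers it stood at 13.9 ± 0.473, 13.6 ± 1.62, 805 ± 51.1 and 65.1 ± 18.8 CPM, with changes of 5.85 ± 0.22 (5.3e-07) and 2.22 ± 0.19 (0.0016). The flower call in libraries labelled heso1-4 urt1-1 was lost when only the 2 groups compared entered the fit (adjusted p = 0.11) and with flower replicates 2 and 3 alone (0.066). The count covers the whole gene span and the place of the insertion is not given in the sources used here, so it does not measure full-length HESO1 mRNA. AT2G39750, which overlaps the end of HESO1 on the opposite strand, stood at 52.6 ± 7.00 CPM in WT flowers and 33.2 ± 2.2 in flowers labelled heso1-4 (−0.66 ± 0.12, edgeR adjusted p = 0.63, DESeq2 0.0076), but at 49.1 ± 1.67 in flowers labelled heso1-4 urt1-1 (−0.10 ± 0.12, edgeR and DESeq2 adjusted p = 1.0). In seeds it stood at −0.28 ± 0.17 and 0.22 ± 0.17 from WT in the same 2 groups (edgeR adjusted p = 1.0 and 0.76). Directions given below for libraries labelled heso1-4 or heso1-4 urt1-1 are drawn from libraries in which the targeted gene went against its label.

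**Figure D1:**
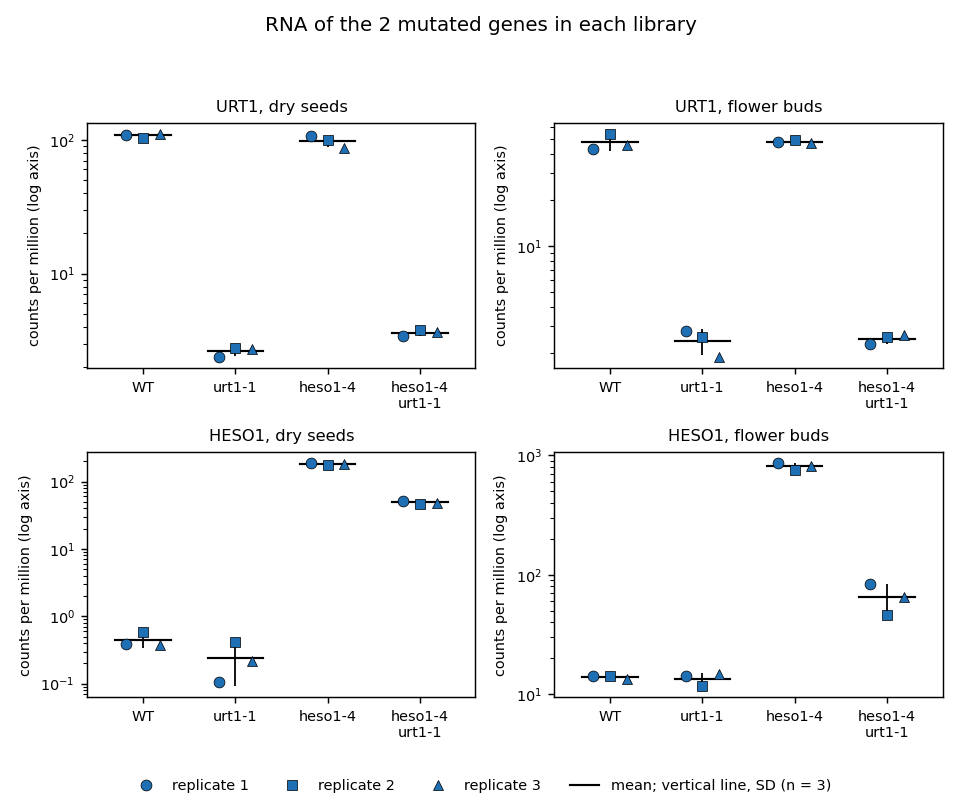
CPM of URT1 (upper panels) and HESO1 (lower panels) in each seed and flower library on log axes, by genotype; points are libraries, horizontal lines means and vertical lines SD (n = 3). URT1 lies between 1.89 and 3.80 CPM in the libraries labelled urt1-1 or heso1-4 urt1-1, and HESO1 in seeds lies between 46.8 and 187 CPM in the libraries labelled heso1-4 or heso1-4 urt1-1 against at most 0.584 in WT.

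In urt1-1 seeds, 4 genes were higher than in WT and 1, URT1 itself, was lower. AT1G64795 (uncharacterised protein, chromosome 1, 24082579 to 24082848), which lies antisense within AT1G64790, rose from 3.91 ± 0.772 CPM (SD, n = 3) in WT to 140 ± 28.4 in urt1-1, while it stood at 2.42 ± 1.22 in libraries labelled heso1-4 and 2.89 ± 0.512 in libraries labelled heso1-4 urt1-1. AT2G34700 (chromosome 2, 14634090 to 14635627), of the pollen Ole e 1 allergen and extensin family of cell wall proteins, rose from 1.66 ± 0.255 to 6.57 ± 1.44 CPM. The precursor gene MIR5642b (AT2G03855, chromosome 2, 2805 to 3176) rose from 102 ± 17.3 to 202 ± 28 CPM and AT2G01008 (chromosome 2, 1025 to 3173), which overlaps it on the same strand, from 211 ± 36.8 to 421 ± 65.0 CPM. The log2 fold changes were 5.15 ± 0.28 for AT1G64795 (edgeR adjusted p = 2.8e-06), 1.98 ± 0.24 for AT2G34700 (0.0032), 0.98 ± 0.14 for MIR5642b (0.024) and 0.99 ± 0.15 for AT2G01008 (0.033), each with all 3 urt1-1 libraries above all 3 WT libraries. The last pair lies in the ribosomal DNA region of chromosome 2, and the libraries were depleted of ribosomal RNA. Ribosomal DNA genes held 0.271% to 1.904% of counts in the urt1-1 seed libraries and 0.298% to 1.357% in WT. Reads in the overlap of this pair count for both genes and a near-identical copy lies on chromosome 3, so their values are uncertain. Among 17939 genes tested, 1238 had an unadjusted p under 0.05, and DESeq2 called 15 up and 2 down. Both calls of the overlapping pair were lost, leaving 2 genes up, without urt1-1 replicate 1 (MIR5642b adjusted p = 0.089, AT2G01008 0.12), without urt1-1 replicate 2 (0.10, 0.15), without WT replicate 2 (0.33, 0.38), without WT replicate 3 (0.19, 0.25), or with only the 2 groups in the fit (0.25, 0.34).

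Same-numbered seed libraries of urt1-1 and WT deviated together, and with the replicate number as a block 73 genes rose and 17 fell, the 5 genes above among them. Of the 73, 24 belonged to a wider list of ribosomal protein genes that was drawn up after the data were seen. With the block in urt1-1 seeds, AT5G23900 (ribosomal protein L13e) rose by 0.76 ± 0.10 (edgeR adjusted p = 0.0069) and AT2G27710 (60S acidic ribosomal protein) by 0.62 ± 0.09 (0.0078). There the ubiquitin gene UBQ5 rose by 0.52 ± 0.08 (0.014) and the cell wall alpha-xylosidase gene XYL1 by 1.07 ± 0.17 (0.015). ICS1, which encodes the isochorismate synthase of salicylic acid synthesis, changed by −0.74 ± 0.12 (0.015), the ethylene synthesis gene ACS6 by −0.81 ± 0.12 (0.0094), the seed maturation regulator BZIP53 by −0.60 ± 0.11 (0.019) and RAP2.6, an ethylene response factor gene, by −0.77 ± 0.13 (0.015). These 8 genes were chosen after their values were seen, and without the block their adjusted p lay between 0.37 and 0.72.

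Of the cytosolic ribosomal protein list, 48 members were measured in seeds with a median log2 fold change of 0.32 in urt1-1. Adjusted over the list alone, 4 members rose, AT2G27710 (0.63 ± 0.13, adjusted p = 0.012), EMB3010 (0.55 ± 0.16, 0.049), RPL27AB (0.43 ± 0.13, 0.049) and RP1 (0.51 ± 0.15, 0.049), against 0 over all genes tested by edgeR. With the replicate block 5 members rose over all genes tested, EMB3010 (0.55 ± 0.09, edgeR adjusted p = 0.014), RPL27AB (0.43 ± 0.09, 0.049) and RP1 (0.50 ± 0.09, 0.021) among them. Camera with its preset correlation placed the list above other genes (adjusted p = 8.2e-17), a call lost with adjusted p = 0.80 with an estimated correlation. It also placed the plastid-encoded genes (median −0.17, 1.4e-07), the mitochondrion-encoded genes (−0.13, 0.019) and the seed storage and oil body proteins (−0.17, 0.019) below other genes, each with adjusted p = 0.80 with an estimated correlation. The plastid share of counts was 6.03% to 6.21% in the urt1-1 seed libraries and 6.92% to 7.76% in WT. The seed storage median was 0.035 without urt1-1 replicate 1 and 0.046 without WT replicate 3. The other 18 lists were not called, with medians from −0.51 to 0.26, the mRNA decay machinery at 0.004, the small RNA machinery at 0.11 and the miRNA and tasiRNA targets at 0.07. Of the seed maturation regulators, FAD2, a fatty acid desaturase gene, stood at 0.47 ± 0.15 and ABI3, a master regulator of seed maturation, at −0.38 ± 0.12, each with edgeR adjusted p = 0.041 when adjusted over the list alone and 0.56 over all genes.

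**Figure D2:**
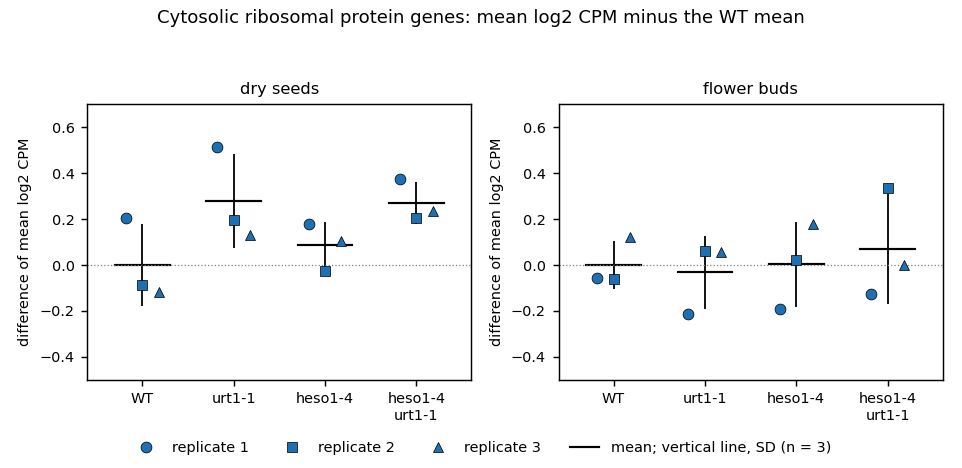
Mean log2 CPM of the cytosolic ribosomal protein list in each library minus the mean of the 3 WT libraries of its tissue, by genotype; points are libraries, horizontal lines means and vertical lines SD (n = 3). In seeds the urt1-1 libraries lie between 0.132 and 0.513 and WT between −0.118 and 0.206, with replicate 1 highest in each genotype.

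In seeds labelled heso1-4, 2 genes were called higher than in WT. Besides HESO1, ARP9 (AT5G43500, actin-related protein 9, chromosome 5, 17469490 to 17473619) rose from 8.19 ± 1.33 CPM (SD, n = 3) to 26.4 ± 1.57, a log2 fold change of 1.69 ± 0.14 (edgeR adjusted p = 4.0e-05), with all 3 libraries above all 3 WT libraries. With edgeR, 0 genes were called lower, DESeq2 called 3 higher and 0 lower, and 675 genes had an unadjusted p under 0.05. Neither gene lost its call in any alternative run. Camera called 4 lists, the heat shock proteins (median 0.17, adjusted p = 0.038), photosynthesis genes (0.14, 0.038), plastid-encoded genes (0.15, 1.7e-06) and cytosolic ribosomal proteins (0.13, 9.2e-05), each lost with adjusted p = 0.97 with an estimated correlation. By edgeR, 0 members of these lists passed, over all genes or over the list alone. The call count was 8 lists without WT replicate 1, 1 without WT replicate 3 and 7 without replicate 3 labelled heso1-4. That library stood apart in its composition, with 9.53% of its counts on AT2G41310 and 9.05% on AT1G15405, against at most 5.29% and 3.71% in any other seed library. The other 18 lists had medians from −0.38 to 0.46.

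In seeds labelled heso1-4 urt1-1, 7 genes were higher and 3 lower than in WT. HESO1 and ARP9 were higher, ARP9 at 25.3 ± 1.67 CPM (1.62 ± 0.14, edgeR adjusted p = 4.1e-05), and AT2G34700 stood at 7.33 ± 1.17 CPM (2.13 ± 0.24, 0.00053). AT2G16586 (uncharacterised protein, chromosome 2, 7190937 to 7192071) rose from 5.95 ± 2.46 to 43.7 ± 3.29 CPM (2.89 ± 0.30, 0.0013), and AT5G24240 (phosphatidylinositol 4-kinase gamma-like protein, chromosome 5, 8230916 to 8234150) from 1.32 ± 0.413 to 6.30 ± 1.82 CPM (2.25 ± 0.32, 0.0083). MIR5642b stood at 315 ± 22.4 CPM (1.62 ± 0.14, 4.9e-05) and AT2G01008 at 670 ± 52.4 (1.66 ± 0.15, 6.4e-05), while MIR5642a (AT3G06345, chromosome 3, 14196774 to 14197147), the near-identical copy in the ribosomal DNA of chromosome 3, fell from 757 ± 109 CPM to 321, 309 and 282 CPM in the 3 libraries (−1.32 ± 0.14, 0.00038). AT2G45630 (dehydrogenase family protein, chromosome 2, 18795926 to 18797263), which starts just downstream of URT1, fell from 1.64 ± 0.281 to 0.0589 ± 0.0529 CPM (−4.67 ± 0.72, 0.018). In urt1-1 alone it stood at 0.193 ± 0.122 CPM and was not called (−3.09 ± 0.63, adjusted p = 0.32), but was with the replicate block (−3.16 ± 0.60, 0.029). In flowers, where it stood at 8.10 ± 1.47 CPM in WT, it was not called in urt1-1 (−0.57 ± 0.18) or in libraries labelled heso1-4 urt1-1 (−0.67 ± 0.18, edgeR adjusted p = 1.0 each). Unadjusted p lay under 0.05 for 1546 genes, and DESeq2 called 55 up and 19 down. The AT5G24240 call was lost without WT replicate 1 (0.071), WT replicate 2 (0.12) or replicate 3 labelled heso1-4 urt1-1 (0.074), and the AT2G45630 call without WT replicate 1 (0.068), WT replicate 2 (0.12) or replicate 1, 2 or 3 labelled heso1-4 urt1-1 (0.093, 0.11, 0.074).

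Camera called 6 lists in seeds labelled heso1-4 urt1-1, each lost with adjusted p = 0.67 with an estimated correlation, and edgeR called 0 of their members over all genes. The cytosolic ribosomal proteins had a median of 0.32 (camera adjusted p = 4.2e-16), and 7 of 48 members rose adjusted over the list alone, among them AT2G27710 (0.59 ± 0.13, 0.020) and RP1 (0.57 ± 0.15, 0.031), against edgeR adjusted p of 0.20 and 0.32 over all genes. Of 15 heat shock proteins (median 0.15, camera 0.0026), HSP21 (1.53 ± 0.31, 0.0026), HSP22.0 (1.44 ± 0.36, 0.017), HSP17.6B (0.57 ± 0.16, 0.017) and HSP17.6C (0.48 ± 0.16, 0.035) rose adjusted over the list alone, against edgeR adjusted p of 0.15, 0.36, 0.38 and 0.44 over all genes. Of 8 measured salicylic acid and defence genes (−0.85, 0.027), ICS1 fell (−1.06 ± 0.26, 0.011 adjusted over the list alone, 0.29 over all genes by edgeR), and of 4 measured floral organ identity genes (−0.91, 0.035), SEP1 fell (−1.89 ± 0.61, 0.028 adjusted over the list alone, 0.41 over all genes), a gene at 0.717 CPM in WT seeds. In mean log2 CPM of the defence list minus the WT mean, WT replicates 1, 2 and 3 lay at 0.668, 0.295 and −0.963. The libraries labelled heso1-4 urt1-1 lay at −0.717, −0.827 and −0.68, all above WT replicate 3. For floral organ identity WT lay at 0.719, 0.227 and −0.946, and libraries labelled heso1-4 urt1-1 at −1.032, −0.713 and −0.919. MYB33, a target of miR159, rose among 44 miRNA and tasiRNA targets (0.55 ± 0.10, 0.0021 adjusted over the list alone, 0.068 over all genes by edgeR), a list not called itself (median 0.06, camera adjusted p = 0.27). Plastid-encoded (−0.09, 0.00099) and mitochondrion-encoded genes (−0.20, 5.0e-05) were also called, the plastid median being 0.038 without replicate 2 labelled heso1-4 urt1-1. The other 16 lists had medians from −0.48 to 0.35.

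Libraries labelled heso1-4 urt1-1 were then compared with each single mutant to ask what a further insertion changes. Against urt1-1 seeds, 4 genes were higher (HESO1, ARP9, AT5G24240 and AT2G16586) and 3 lower. AT1G64795 was lower by −5.60 ± 0.28 (edgeR adjusted p = 1.2e-06), MIR5642a by −1.06 ± 0.14 (0.0081), and the non-coding RNA AT1G67105 (chromosome 1, 25057479 to 25058264) fell from 6.24 ± 0.785 to 1.75 ± 0.642 CPM (−1.83 ± 0.27, 0.020). ARP9 was higher by 1.42 ± 0.14 (0.00018), AT5G24240 by 2.09 ± 0.31 (0.020) and AT2G16586 by 1.99 ± 0.28 (0.036). The replicate numbers pair these libraries, and with the block the AT2G16586 call was lost (0.36). Camera called 4 of 22 lists, seed storage and oil body proteins (median 0.16, adjusted p = 0.0023), heat shock proteins (0.14, 0.0057), floral organ identity (−0.96, 0.0023) and mitochondrion-encoded genes (−0.10, 0.027), each with adjusted p = 0.81 with an estimated correlation, and with the block also salicylic acid and defence (0.022) and plastid-encoded genes (0.020). DESeq2 called 6 genes up and 5 down, and 228 had an unadjusted p under 0.05. AT2G16586 lost its call without urt1-1 replicate 2 or 3 (0.50, 0.18) or replicate 1, 2 or 3 labelled heso1-4 urt1-1 (0.25, 0.17, 0.19), AT1G67105 without urt1-1 replicate 1, 2 or 3 (0.10, 0.055, 0.10) or replicate 1 or 2 labelled heso1-4 urt1-1 (0.14, 0.096), AT5G24240 without urt1-1 replicate 1 or 2 (0.10, 0.23) or replicate 2 or 3 labelled heso1-4 urt1-1 (0.13, 0.19), and MIR5642a without replicate 1, 2 or 3 labelled heso1-4 urt1-1 (0.053, 0.096, 0.12). The count was 4 without urt1-1 replicate 2 and 4, 3 and 4 without replicates 1, 2 and 3 labelled heso1-4 urt1-1. With only the 2 groups in the fit, AT5G24240 (0.080) and AT1G67105 (0.078) were lost, and with no filter on low counts AT2G16586 (0.27).

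Against seeds labelled heso1-4, 6 genes were higher and 7 lower in seeds labelled heso1-4 urt1-1. HESO1 (−1.89 ± 0.13, edgeR adjusted p = 2.2e-06) and URT1 were among the lower ones. AT5G24240 (2.74 ± 0.33, 0.0018), AT2G16586 (2.37 ± 0.29, 0.0076) and AT2G01008 (2.25 ± 0.16, 2.2e-06) were higher, and so were MIR5642b (2.22 ± 0.15, 1.8e-06) and AT2G34700 (1.89 ± 0.23, 0.0021), which are named for this comparison after their values were seen. MIR5642a was lower (−1.85 ± 0.14, 6.1e-06). AT2G45630 (−4.22 ± 0.72, 0.047) and AT5G33390 (glycine-rich protein, chromosome 5, 12661708 to 12663496, −4.15 ± 0.71, 0.047) stood at 0.0589 ± 0.0529 and 0.116 ± 0.158 CPM against 1.19 ± 0.601 and 2.19 ± 0.382 in libraries labelled heso1-4. Camera called 4 of 22 lists, salicylic acid and defence (median −1.26, adjusted p = 0.0003), plastid-encoded (−0.30, 2.3e-12) and mitochondrion-encoded genes (−0.28, 6.8e-05) and cytosolic ribosomal proteins (0.19, 8.6e-06), each with adjusted p = 0.73 with an estimated correlation. The replicate numbers pair these libraries too, and with the block 205 genes were called in place of 13, and mature pollen (0.023), jasmonate (0.006) and short-lived stress-responsive lists (0.018) as well. DESeq2 called 44 genes up and 56 down, and 1906 had an unadjusted p under 0.05. The count was 35 without replicate 1 and 7 without replicate 2 labelled heso1-4, and 7 without replicate 1 and 8 without replicate 3 labelled heso1-4 urt1-1. AT2G16586 lost its call without replicate 2 labelled heso1-4 (0.089) or replicate 1 labelled heso1-4 urt1-1 (0.056). AT2G45630 lost its call without replicate 1 or 2 labelled heso1-4 (0.064, 0.14) or replicate 1, 2 or 3 labelled heso1-4 urt1-1 (0.18, 0.21, 0.19), and AT5G33390 without replicate 1, 2 or 3 labelled heso1-4 (0.052, 0.16, 0.092) or replicate 1 or 3 labelled heso1-4 urt1-1 (0.14, 0.31). Both were lost with only the 2 groups in the fit (0.14 each), and AT2G16586 with no filter on low counts (0.054).

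A departure from additivity of the 2 insertions in seeds was called for 2 genes. For AT1G64795 the interaction was −4.90 ± 0.41 (edgeR adjusted p = 0.00067), and for MIR5642a, which overlaps AT3G06325 on the same strand and is uncertain, it was −1.59 ± 0.20 (0.0075). DESeq2 called 3 positive and 2 negative interactions, and 368 genes had an unadjusted p under 0.05. With the replicate block AT5G24240, named here after its values were seen, was also called (2.54 ± 0.36, edgeR adjusted p = 0.016, and 0.21 without the block). Not all groups that enter the interaction are paired by the criterion used. The MIR5642a call was lost without WT replicate 2 or replicate 3 labelled heso1-4 urt1-1 (0.062 each), leaving 1 gene, and 4 genes were called without urt1-1 replicate 1. Camera called 4 lists for the interaction, seed storage and oil body proteins (median 0.29, adjusted p = 0.0078), salicylic acid and defence (−1.14, 0.017), plastid-encoded genes (−0.09, 0.047) and cytosolic ribosomal proteins (−0.14, 0.012), each with adjusted p = 0.80 with an estimated correlation. Of the counts on both MIR5642 precursors together, the chromosome 2 copy held 11.9% ± 0.4 (SD, n = 3) in WT seeds, 24.2% ± 0.6 in urt1-1, 5.9% ± 0.8 in libraries labelled heso1-4 and 50.9% ± 1.7 in libraries labelled heso1-4 urt1-1. In flowers the shares were 13.2% ± 1.8, 28.3% ± 0.7, 7.2% ± 3.9 and 37.1% ± 4.6, the same order of genotypes. Each share rests on at least 4325 counts per library.

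**Figure D3:**
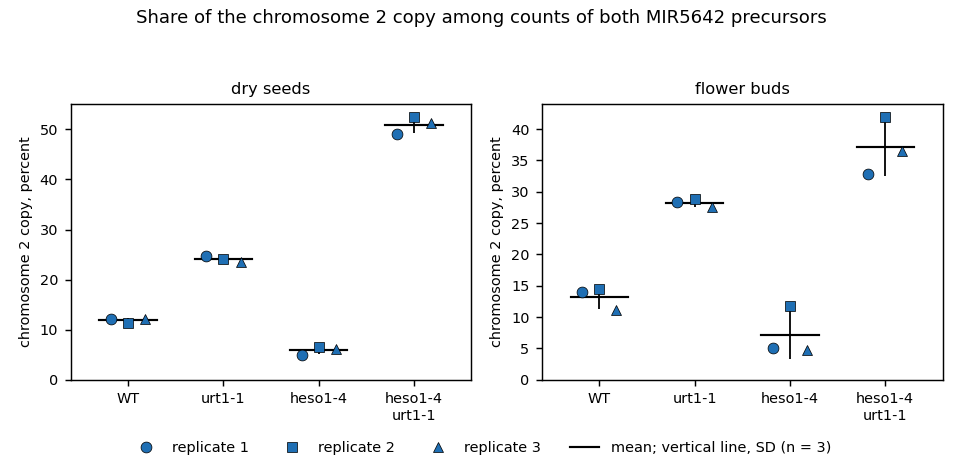
Share, in percent, of the chromosome 2 copy (MIR5642b) among the counts of MIR5642a and MIR5642b in each library, by genotype, for seeds and flower buds; points are libraries, horizontal lines means and vertical lines SD (n = 3). In seeds the 4 genotypes do not overlap, with means of 5.9% in libraries labelled heso1-4, 11.9% in WT, 24.2% in urt1-1 and 50.9% in libraries labelled heso1-4 urt1-1.

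In urt1-1 flowers, 1 gene was higher and 1, URT1, lower than in WT. The higher gene was again AT1G64795, which rose from 0.201 ± 0.120 CPM (SD, n = 3) to 16.6 ± 1.68 (6.32 ± 0.44, edgeR adjusted p = 0.00017), with all 3 libraries above all 3 WT libraries. It stood at 0.0883 ± 0.0543 CPM in libraries labelled heso1-4 and 0.243 ± 0.118 in libraries labelled heso1-4 urt1-1. Among 22841 genes tested, 593 had an unadjusted p under 0.05, and DESeq2 called 5 up and 1 down. Without urt1-1 replicate 3, 2 genes were called up. Camera called 10 of 22 lists, each lost with adjusted p of 0.57 to 0.78 with an estimated correlation. Above other genes lay seed coat genes (median 0.87, adjusted p = 0.014), salicylic acid and defence genes (0.51, 0.0053), short-lived stress-responsive mRNAs (0.50, 0.00022), late embryogenesis abundant and abscisic acid-responsive genes (0.42, 0.0049), seed storage and oil body proteins (0.28, 0.010) and photosynthesis genes (0.09, 0.044, and 0.12 with the replicate block). Below them lay tapetum and early anther genes (−0.55, 0.00081), plastid-encoded genes (−0.09, 0.0027), the small RNA machinery (−0.07, 0.010) and miRNA and tasiRNA targets (−0.03, 0.044). EdgeR called 0 members of any of these 10 lists, over all genes or over the list alone. The tapetum score of urt1-1 replicate 1 lay at −1.80 relative to the WT mean, against −0.03 and 0.05 in the other libraries of that group, and its seed coat score at 2.24. The seed coat median was −0.11 without that library, 0.61 without WT replicate 2 and 0.68 without WT replicate 3. Without urt1-1 replicate 1, urt1-1 replicate 2 and WT replicate 3 in turn, 5, 6 and 0 lists were called, and the plastid median was −0.015, −0.028 and 0.032. The other 12 lists had medians from −0.08 to 0.66.

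In flowers labelled heso1-4, HESO1 and ARP9 were higher than in WT. ARP9 rose from 14.9 ± 1.62 CPM (SD, n = 3) to 38.6 ± 2.59 (1.37 ± 0.12, edgeR adjusted p = 0.0013), all 3 libraries above all 3 WT libraries, and its call was lost with only the 2 groups in the fit (0.050). EdgeR called 0 genes lower, DESeq2 5 higher and 3 lower, and 623 genes had an unadjusted p under 0.05. With the replicate block AT5G41740, a disease resistance gene of the TIR-NBS-LRR class named after its values were seen, was also called (1.92 ± 0.24, edgeR adjusted p = 0.042, and 1.0 without the block). Camera called 6 lists, the short-lived stress-responsive mRNAs (median 1.12, adjusted p = 2.3e-19), the salicylic acid and defence genes (1.104, 7.7e-06), photosynthesis genes (0.34, 5.7e-10), jasmonate genes (0.24, 0.010) and plastid-encoded genes (0.08, 0.0084) above other genes and mature pollen genes (−0.45, 0.020) below them. With an estimated correlation their adjusted p lay between 0.22 and 0.91. By edgeR, 0 of their members passed, over all genes or over the list alone. The transcription factor genes ZAT12 (1.14 ± 0.37), ERF6 (1.62 ± 0.57), ZAT10 (1.5 ± 0.55) and WRKY40 (1.69 ± 0.66) each had an edgeR adjusted p = 0.14 when adjusted over the list alone. The defence score of replicate 1 labelled heso1-4 lay 2.54 above the WT mean, against 0.07 and 0.61 in the other libraries of that group, and the stress scores of the 3 WT libraries ranged from −0.79 to 1.18 around their own mean. The plastid median was −0.02 without WT replicate 1 or replicate 3 labelled heso1-4. The other 16 lists had medians from −0.18 to 0.25.

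In flowers labelled heso1-4 urt1-1, HESO1 and ARP9 were higher and URT1 lower than in WT. ARP9 stood at 35.2 ± 2.21 CPM (1.24 ± 0.12, edgeR adjusted p = 0.0024), a call lost with only the 2 groups in the fit (0.11) and with flower replicates 2 and 3 alone (0.051). DESeq2 called 15 up and 0 down, giving no adjusted p for URT1 or ARP9, edgeR gave 646 genes an unadjusted p under 0.05, and 2 genes were called down without replicate 3 of that group. Camera called 10 lists, each lost with adjusted p of 0.73 to 0.83 with an estimated correlation. Above other genes lay salicylic acid and defence genes (0.88, 0.00024), short-lived stress-responsive mRNAs (0.59, 5.8e-06), the mRNAs known to be prone to siRNA production (0.36, 0.020), photosynthesis (0.16, 0.0079), cell division (0.12, 0.030) and mitochondrion-encoded genes (0.10, 0.0079) and cytosolic ribosomal proteins (0.06, 0.016). Below them lay tapetum and early anther (−0.56, 0.016), mature pollen (−0.40, 0.048) and plastid-encoded genes (−0.09, 0.0011). By edgeR, 0 members of these lists passed, over all genes or over the list alone. The count of lists was 5 without WT replicate 3 or without replicate 1 labelled heso1-4 urt1-1, where the plastid medians were 0.02 and −0.045. The ribosomal protein median was −0.08 without replicate 2 labelled heso1-4 urt1-1, 0.05 without WT replicate 1 and 0.06 without WT replicate 2. The other 12 lists had medians from −0.06 to 0.38.

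Against urt1-1 flowers, libraries labelled heso1-4 urt1-1 had higher HESO1 and ARP9 (1.21 ± 0.12, edgeR adjusted p = 0.0031) and lower AT1G64795 (−6.10 ± 0.43, 0.00043). The ARP9 call was lost with only the 2 groups in the fit (0.23) and with flower replicates 2 and 3 alone (0.11). DESeq2 called 2 up and 2 down, and 318 genes had an unadjusted p under 0.05. Camera called 9 lists. Higher were the mRNA decay machinery (median 0.09, adjusted p = 0.0042), small RNA machinery (0.13, 0.00073), miRNA and tasiRNA targets (0.06, 0.028), siRNA-prone mRNAs (0.25, 0.0062), cell division (0.20, 0.00073), mitochondrion-encoded genes (0.11, 0.00024) and cytosolic ribosomal proteins (0.09, 0.0042), and lower were late embryogenesis abundant genes (−0.24, 0.0042) and heat shock proteins (−0.24, 0.023), with adjusted p of 0.38 to 0.83 with an estimated correlation. The replicate numbers pair these libraries, and with the block the heat shock call was lost (0.088) and mature pollen (0.0059), seed coat (0.00011) and salicylic acid and defence (0.027) were called. Against flowers labelled heso1-4, URT1, HESO1 and AT3G41979, a 5.8S ribosomal RNA gene (chromosome 3, 14199753 to 14199916) that overlaps another annotated gene, were lower, the last from 3.89 ± 0.828 to 0.677 ± 0.230 CPM (−2.52 ± 0.31, 0.043). EdgeR called 0 genes higher there, and with the replicate block AT2G16586, named here after its values were seen (1.69 ± 0.20, adjusted p = 0.023, and 0.81 without the block). DESeq2 called 17 higher and 6 lower, and 644 genes had an unadjusted p under 0.05. AT3G41979 lost its call with only the 2 groups (0.75), with flower replicates 2 and 3 alone (1.0) and without replicate 1 or 3 labelled heso1-4 (0.27, 0.28) or replicate 1, 2 or 3 labelled heso1-4 urt1-1 (0.052, 0.28, 0.38), and 5 genes were called without replicate 2 labelled heso1-4. Camera called photosynthesis (median −0.26, adjusted p = 0.0011), short-lived stress-responsive (−0.49, 1.5e-06) and plastid-encoded genes (−0.18, 3.1e-10) lower, each with adjusted p = 0.95 with an estimated correlation. With the block, which pairs these libraries too, tapetum (0.023), seed coat (0.0017), jasmonate (0.042), mitochondrion-encoded (0.033) and cytosolic ribosomal protein lists (0.034) were also called. The interaction in flowers was called for HESO1 alone (−3.59 ± 0.27, 0.00069), with 436 genes at an unadjusted p under 0.05 and 3 calls by DESeq2. Camera called 10 lists for it, with adjusted p of 0.45 to 0.76 with an estimated correlation. These were the mRNA decay machinery (median 0.08, adjusted p = 0.037), small RNA machinery (0.20, 0.0015), mitochondrion-encoded genes (0.13, 0.029), seed storage (−0.46, 0.034), late embryogenesis abundant (−0.59, 0.0084), heat shock (−0.46, 0.019), photosynthesis (−0.35, 5.1e-05), salicylic acid and defence (−0.70, 0.0084), short-lived stress-responsive (−0.98, 8.3e-11) and plastid-encoded genes (−0.10, 0.029).

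**Figure D4:**
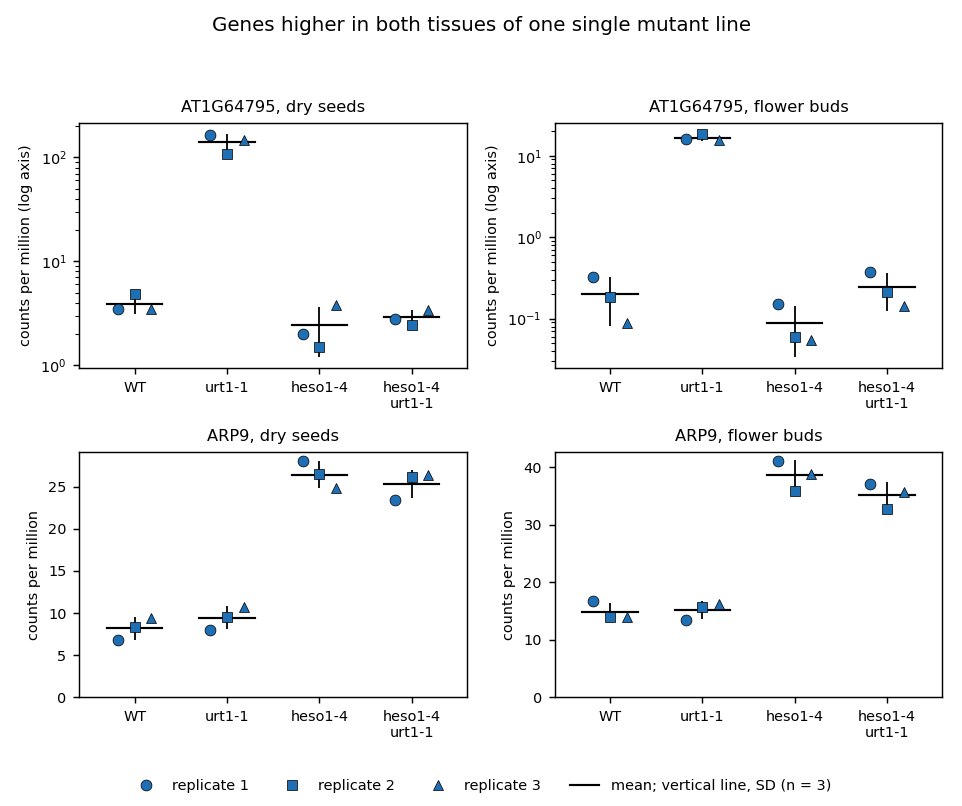
CPM of AT1G64795 (upper panels, log axes) and ARP9 (lower panels, linear axes from 0) in each library, by genotype and tissue; points are libraries, horizontal lines means and vertical lines SD (n = 3). AT1G64795 is high in urt1-1 alone, at means of 140 CPM in seeds and 16.6 in flowers, and ARP9 is high in both groups labelled as carrying heso1-4, at 25.3 and 26.4 CPM in seeds against 8.19 in WT.

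Genes called in both tissues were AT1G64795 and URT1 for urt1-1, HESO1 and ARP9 for libraries labelled heso1-4, and HESO1, ARP9 and URT1 for libraries labelled heso1-4 urt1-1. Among 17281 genes tested in both tissues, the log2 fold changes correlated across genes, which are not independent replicates, at 0.02, 0.05 and 0.06 for the 3 genotypes. A joint fit over 24 libraries and 23557 genes tested whether a genotype's change differed between tissues. For urt1-1, edgeR called 0 genes, with 1292 at an unadjusted p under 0.05, 6 called by DESeq2, 4 with separate fits of each tissue and 2 with the replicate number as a block within tissue, and the fall of URT1 differed by 1.04 ± 0.17 between flowers and seeds (adjusted p = 0.092). Without flower urt1-1 replicate 3, 1 gene was called. By edgeR without a block, HESO1 was the 1 gene called for libraries labelled heso1-4 (flower minus seed −2.78 ± 0.32, 0.00077) and for libraries labelled heso1-4 urt1-1 (−4.52 ± 0.32, 1.4e-07), its rise being smaller in flowers on the log2 scale. DESeq2 called 1 and 16 genes there and separate fits of each tissue 1 and 8, 1015 and 1363 genes had an unadjusted p under 0.05, and 2 genes were called for libraries labelled heso1-4 without flower WT replicate 2. HESO1 stood at 0.452 CPM in WT seeds, near the floor, and at 13.9 CPM in WT flowers, so its log2 changes start from unlike levels. Tissue is confounded with the extraction method in the comparison of tissues.

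Between genotypes of one tissue, 4 seed calls were shared by urt1-1 and libraries labelled heso1-4 urt1-1 (AT2G34700, MIR5642b, AT2G01008 and URT1). Independent lists would share 0.0016 up and 0.00017 down, but both comparisons use the same WT libraries, so their lists are not independent. URT1, the shared fall, carries an insertion in both groups, and MIR5642b and AT2G01008 share reads where they overlap. The count of shared calls was 2 without WT replicate 2 or 3, which enter both comparisons. With the replicate block 77 calls were shared, 64 up and 13 down, against 0.63 and 0.049 for independent lists, which these are not. Same-numbered seed libraries labelled heso1-4 urt1-1 and WT were not paired by the criterion (lowest correlation 0.07). No simulated value was drawn for the blocked fit. The log2 fold changes of the 2 comparisons correlated across genes at 0.69, against 0.52 for simulated unchanged groups set against the same WT libraries, with a covariance of 0.113 against 0.060. For urt1-1 and libraries labelled heso1-4 the seed values were 0.38 against 0.50, with a covariance of 0.053 against 0.060, and 0 shared calls. For libraries labelled heso1-4 and heso1-4 urt1-1 they were 0.35 against 0.51, 0.054 against 0.060, and 2 shared calls (HESO1 and ARP9). In flowers, urt1-1 and libraries labelled heso1-4 urt1-1 shared 1 call (URT1), with a correlation of 0.69 against 0.49 and a covariance of 0.126 against 0.097. For urt1-1 and libraries labelled heso1-4 the flower values were 0 shared calls, 0.55 against 0.50 and 0.102 against 0.099, and for libraries labelled heso1-4 and heso1-4 urt1-1 they were 2 shared calls (HESO1 and ARP9), 0.65 against 0.51 and 0.116 against 0.10. With 3 WT libraries per tissue the controls could not be split into parts of at least 2, so part of any excess may come from the shared WT libraries. The simulated libraries were drawn independently, without the shared deviations of same-numbered libraries, so the simulated values do not cover what those add.

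Over the 6 comparisons of a genotype with WT, 4 of the 22 lists fixed before the data were examined were never called by camera. These were the mRNA decay machinery (medians −0.041 to 0.046, lowest adjusted p = 0.17), dormancy and germination control (−0.125 to 0.195, 0.46), endosperm (0.231 to 0.655, 0.097) and seed maturation regulators and fatty acid synthesis (−0.080 to −0.016, 0.23). Called once were small RNA machinery (−0.082 to 0.107), miRNA and tasiRNA targets (−0.031 to 0.072), siRNA-prone mRNAs (0.059 to 0.364), late embryogenesis abundant and abscisic acid-responsive genes (−0.115 to 0.423), floral organ identity (−0.908 to 0.128), seed coat (−0.478 to 0.870), jasmonate (−0.132 to 0.244) and cell division (−0.057 to 0.277). Seed storage and oil body proteins (−0.168 to 0.283), heat shock proteins (0.083 to 0.292), tapetum and early anther (−0.563 to 0.124) and mature pollen (−0.513 to 0.425) were called in 2 comparisons, and short-lived stress-responsive mRNAs (−0.208 to 1.115) and mitochondrion-encoded genes (−0.199 to 0.10) in 3. Photosynthesis (−0.041 to 0.340), salicylic acid and defence (−0.848 to 1.104) and cytosolic ribosomal proteins (−0.013 to 0.323) were called in 4, and plastid-encoded genes (−0.170 to 0.154) in 6. The lowest adjusted p of any of the 22 with an estimated correlation was 0.22. Median, mean and camera's direction differed in sign only for lists not called in the 6 comparisons with WT. In urt1-1 seeds these were the mRNA decay machinery (median 0.004, mean 0.018, camera lower) and photosynthesis (−0.041, 0.023, higher). In seeds labelled heso1-4 they were late embryogenesis abundant genes (0.010, −0.015, lower), maturation regulators (−0.032, 0.015, lower), tapetum (0.124, 0.038, lower), endosperm (0.457, 0.158, lower) and mitochondrion-encoded genes (0.026, −0.009, higher), and in seeds labelled heso1-4 urt1-1 maturation regulators (−0.070, 0.042, higher). In urt1-1 flowers they were the mRNA decay machinery (−0.039, 0.006, lower), siRNA-prone mRNAs (0.059, 0.097, lower), mature pollen (0.039, −0.066, lower), jasmonate (−0.035, −0.021, higher) and ribosomal proteins (−0.013, −0.026, higher). In flowers labelled heso1-4 they were the mRNA decay machinery (−0.020, 0.043, lower), miRNA and tasiRNA targets (0.019, −0.031, lower), dormancy (0.043, −0.001, lower) and seed coat (−0.013, 0.030, lower), and in flowers labelled heso1-4 urt1-1 late embryogenesis abundant genes (−0.056, −0.099, higher) and heat shock proteins (0.083, 0.198, lower). The wider ribosomal protein list, drawn up after the data were seen, had 277 members tested in seeds, with a median of 0.295 in urt1-1 (p = 0.031 with an estimated correlation), 0.295 in libraries labelled heso1-4 urt1-1 (0.026) and 0.115 in libraries labelled heso1-4 (0.21), and adjusted over the list alone 21, 13 and 0 members rose. Its flower medians over 287 members were −0.007, 0.034 and 0.021 in the same order, with p = 0.97, 0.73 and 0.91 with an estimated correlation.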

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

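All tests of explanations and all counts of other splits below were chosen after the results were seen, except the test of gene length and expression level, which was set before. Its matched lists, however, left out the members of the wider ribosomal protein list, which was drawn up after the data were seen. The test of the difference itself picked out 5 results, and single libraries that stand apart were not tested for in groups of 3.

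The change of HESO1 differed between tissues, by −2.78 ± 0.32 on the log2 scale (edgeR adjusted p = 0.00077) for libraries labelled heso1-4 and by −4.52 ± 0.32 (1.4e-07) for libraries labelled heso1-4 urt1-1. In WT, HESO1 stood at 0.452 CPM in seeds (8, 18 and 9 counts), near the floor, and at 13.9 CPM in flowers. The log2 changes thus start from unlike levels. In seeds the changes from WT in libraries labelled heso1-4 and urt1-1 did not add up for AT1G64795, with an interaction of −4.90 ± 0.41 (0.00067), nor for MIR5642a, with −1.59 ± 0.20 (0.0075), and in flowers not for HESO1, with −3.59 ± 0.27 (0.00069).

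HESO1 RNA was lower in libraries labelled heso1-4 urt1-1 than in libraries labelled heso1-4, 3.71-fold in seeds and 12.4-fold in flowers. Normalization is argued against, since with no scaling of the counts HESO1 still stood at −1.23 in seeds and −3.74 in flowers on the log2 scale, with no overlap of the 2 groups. Plants with a wild-type HESO1 allele in the pools stay open as a candidate explanation: ARP9 kept 93.8% of its rise in seeds and 85.4% in flowers where HESO1 kept 26.8% and 6.5%, but ARP9 lies on chromosome 5 and HESO1 on chromosome 2, so both may segregate separately. Silencing of insertion-driven transcripts when both insertions are present stays open too, since AT1G64795 stood at −0.45 ± 0.28 from WT in seeds with both insertions, but its raised copy on chromosome 1 could have been lost in crossing. A loss of HESO1 function was not tested.

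The 2 MIR5642 copies, of 372 and 374 bases and 6 edits apart, went opposite ways in seeds labelled heso1-4 urt1-1. Unequal removal of ribosomal RNA is argued against: between libraries of one seed genotype the share of counts on 13 other genes of the ribosomal DNA differed from 5.27-fold to 25.2-fold, while the share of the chromosome 2 copy differed by at most 3.3 percentage points, against 39 between WT and libraries labelled heso1-4 urt1-1. Exchange of reads between the copies by the aligner cannot be told apart from a change of both. Their sum changed by −0.48 on the log2 scale in seeds labelled heso1-4 urt1-1. The sum stood at 861 ± 129 CPM (SD, n = 3) in WT seeds, 834 ± 96.8 in urt1-1 and 1160 ± 135 in libraries labelled heso1-4. In flowers it stood at 233 ± 15.6 in WT and 186 ± 18.9 in urt1-1. Flowers labelled heso1-4 and heso1-4 urt1-1 stood at 228 ± 47.9 and 234 ± 60.5. In urt1-1 seeds and flowers labelled heso1-4 urt1-1 the sum thus lay near WT while the share was higher, as exchange would give. Lines that carry or use different ribosomal DNA copies may account for the shift in share: the order of the 4 genotype means was the same in flowers. There the chromosome 2 copy held 37.1% in libraries labelled heso1-4 urt1-1, but replicate 2 labelled heso1-4 (11.7%) lay above WT replicate 3 (11.1%). Exchange in both tissues could give the same order, so the order does not tell these 2 explanations apart.

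Camera placed the cytosolic ribosomal protein list above other genes in urt1-1 seeds and seeds labelled heso1-4 urt1-1 against WT, a call lost with adjusted p = 0.80 and 0.67 with an estimated correlation, and edgeR called 0 of its 48 members over all genes without the block. Camera also placed it above other genes in seeds labelled heso1-4 (median 0.125, adjusted p = 9.2e-05, and 0.97 with an estimated correlation), where URT1 RNA was not called lower. Gene length and expression level are argued against: of 10000 matched lists 0 reached the list's medians of 0.323 and 0.317, their highest medians being 0.115 and 0.144 (0.01% is the smallest share that 10000 lists can give). The matched lists were drawn from genes outside the wider ribosomal protein list, so they hold no other ribosomal protein genes of that list. With only nuclear genes the smaller median was 0.316. TMM sets the scaling by the bulk of genes in both runs, so leaving these counts out could hardly have moved the median. That run therefore does not decide about the share of organellar and ribosomal RNA counts. Seed lots that differ in maturity may be a source and stay open, since the seed storage list moved by −0.168 in urt1-1 and −0.013 in libraries labelled heso1-4 urt1-1. An effect of URT1 loss itself remains a hypothesis.

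For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 5, 2, 10, 7 and 13 genes in seeds (urt1-1, libraries labelled heso1-4 and heso1-4 urt1-1 against WT, then the last against each single mutant), and the highest of the other splits 1, 0, 0, 0 and 0. In flowers the real counts were 2, 2, 3, 3 and 3 and the highest other 0 in each. In each of these 10 comparisons 1 split, the real one, reached the real count. The real counts include URT1, HESO1 or both, whose levels follow the labels and are mixed in other splits. Without these genes, 1 gene up and 0 down remained in each flower comparison with WT. In seeds 4 up and 0 down, 1 and 0, and 6 and 2 remained against WT. The splits therefore say little about the other genes in flowers. Of lists, the real split called 4, 4, 6, 4 and 4 in seeds and the highest other 10, 9, 12, 8 and 12, with 6, 9, 4, 5 and 6 splits as high. In flowers it called 10, 6, 10, 9 and 3 and the highest other 9, 12, 10, 9 and 7, with 1, 7, 2, 2 and 9 splits as high. With an estimated correlation 0 lists were called in the comparisons with WT, so these list counts there rest on camera's preset correlation. They do not set the real grouping apart where other splits called 10 lists against 4 for urt1-1 seeds. The same holds for 12 against 4 in seeds labelled heso1-4 urt1-1 against heso1-4. In the 7 paired comparisons those splits part 1 pair of same-numbered libraries, and among splits that part all 3 pairs the highest other list counts were 4, 4 and 8 in seeds (urt1-1 against WT, then libraries labelled heso1-4 urt1-1 against each single mutant) and 7, 7, 4 and 6 in flowers (urt1-1 and libraries labelled heso1-4 against WT, then the same pairs). In each of those seed comparisons, and in some of the flower ones, these reach or exceed the real list count. Among the 4 splits that part all 3 pairs, the real one called 90 genes with the replicate block for urt1-1 seeds against WT and 205 for seeds labelled heso1-4 urt1-1 against heso1-4, and the highest other 0 and 3. For flowers labelled heso1-4 urt1-1 against WT, not paired by the criterion, the real one called 4 genes and the highest other 8.

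The interaction in flowers (1 gene) was reached by 1 of 40 splits, the highest other being 0. That gene was HESO1, whose level differs strongly between genotypes. These splits shuffled all 4 genotypes, which mixes its levels within each group, so they do not stand for data without an interaction. They were also drawn without regard to replicate numbers, by which most pairs of flower groups deviate together. They therefore cannot decide about chance for this count. In seeds (2 genes) the interaction was reached by 3 of 40, the highest other being 7. These splits mixed the 4 genotypes in the same way, so they cannot decide about chance for that count either, and it is not excluded. Nor can chance be excluded for the counts of genes that differed between tissues in libraries labelled heso1-4 and heso1-4 urt1-1. There 2 and 3 of 33 splits reached the real counts of 1 and 1, the highest others being 1 and 3. For urt1-1 the real count was 0, which all 33 of 33 splits reach by construction (highest other 6), so that count says nothing about chance. These counts do not weigh single genes: over the alternatives run, the highest adjusted p was 0.016 for AT1G64795 in the seed interaction and 0.011 and 2.3e-06 for HESO1 between tissues in libraries labelled heso1-4 and heso1-4 urt1-1, while MIR5642a reached 0.062.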

How the results depend on the processing

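Halved counts, the fit without the third seed library labelled heso1-4, flower replicates 2 and 3 only and the wider ribosomal protein list were chosen after seeing the data; the other alternatives were planned. Over all alternatives, 501 counts and overlaps stayed within 1.5 times and 94 moved further, 633 values of named genes kept their direction and call and 90 lost the call, with no change of direction, and 430 list values kept direction and call, 191 lost the call and 8 changed direction. Unless said otherwise the cause was not tested. In data simulated at these depths, 38% of 1.5-fold changes were recovered for urt1-1 against WT in seeds and 10% in flowers. These shares may be higher than in the real comparisons, since many more genes were changed there than were called. Depth was not tested apart from the spread between libraries.

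With DESeq2's Wald test, calls rose from 4 to 15 up and 1 to 2 down for urt1-1 seeds, from 7 to 55 up and 3 to 19 down for seeds labelled heso1-4 urt1-1, from 7 to 11 against urt1-1, from 13 to 100 against libraries labelled heso1-4, and from 2 to 5 for the seed interaction. In flowers they went from 1 to 5 up in urt1-1, from 2 to 5 up and 0 to 3 down in libraries labelled heso1-4, from 2 to 15 up and 1 to 0 down in libraries labelled heso1-4 urt1-1, from 3 to 23 for the latter against libraries labelled heso1-4, and from 1 to 3 for the interaction. Shared calls of urt1-1 and libraries labelled heso1-4 urt1-1 went from 4 to 12 in seeds and 1 to 2 in flowers, those of libraries labelled heso1-4 and heso1-4 urt1-1 in flowers from 2 to 1, and those of libraries labelled heso1-4 urt1-1 in both tissues from 3 to 5. Differences between tissues went from 0 to 6 for urt1-1 and from 1 to 16 for libraries labelled heso1-4 urt1-1, lists called from 4 to 2 in urt1-1 seeds and from 10 to 4 in flowers labelled heso1-4 urt1-1.

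With the replicate block, 73 genes rose and 17 fell in urt1-1 seeds, 205 were called for seeds labelled heso1-4 urt1-1 against heso1-4, and 77 calls were shared by urt1-1 and libraries labelled heso1-4 urt1-1. Same-numbered libraries were not paired by the criterion used for seeds labelled heso1-4 and WT (lowest correlation 0.09), seeds labelled heso1-4 urt1-1 and WT (0.07) or the same in flowers (0.06); there the block gave 154 up and 52 down in seeds labelled heso1-4 urt1-1, the list calls of photosynthesis (adjusted p = 0.21) in seeds labelled heso1-4 and floral organ identity (0.084) in seeds labelled heso1-4 urt1-1 were lost, and seed coat (0.00081) was called in flowers labelled heso1-4 urt1-1. All 12 libraries of each tissue correlated best on average with their own number, a hint from the data and not the design. With the block within tissue, 2, 3 and 14 genes differed between tissues for urt1-1 and libraries labelled heso1-4 and heso1-4 urt1-1. In the 7 paired comparisons, AT2G16586 against urt1-1 seeds was the only gene called without the block that lost its call with it, and of calls of the 22 lists the block changed no other than those given beside the results.

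With only the 2 groups compared, which leaves fewer libraries to estimate the spread, 2 genes rose in urt1-1 seeds, 1 in flowers labelled heso1-4 and 0 in flowers labelled heso1-4 urt1-1, 1 was called for the latter against urt1-1, and 1 call each was shared between tissues for libraries labelled heso1-4 and heso1-4 urt1-1. A log2 fold change of at least 1 left 2 genes up in urt1-1 seeds and 2 shared with libraries labelled heso1-4 urt1-1. With no filter, 5 genes showed a seed interaction and 2 lists each were called for urt1-1 seeds and seeds labelled heso1-4. With nuclear genes only, 2 lists were called for urt1-1 seeds, since the plastid- and mitochondrion-encoded lists then have no members. With an estimated correlation, and with fry, 0 lists were called in each of the 6 comparisons with WT, in place of 4, 4 and 6 in seeds and 10, 6 and 10 in flowers by camera. With flower replicates 2 and 3 only, 0 genes rose and 6 lists were called in flowers labelled heso1-4 urt1-1, 1 gene was called against urt1-1, 0 calls were shared with libraries labelled heso1-4 and 1 between tissues. With separate tissue fits and a z test, 4 and 8 genes differed between tissues for urt1-1 and libraries labelled heso1-4 urt1-1, and with halved counts, or without the third seed library labelled heso1-4, 2 for the latter.

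Leaving out 1 library at a time gave 2 to 4 genes up in urt1-1 seeds, 3 to 5 and 7 to 35 genes for seeds labelled heso1-4 urt1-1 against urt1-1 and heso1-4, 1 to 4 for the seed interaction, 2 to 4 shared calls of urt1-1 and libraries labelled heso1-4 urt1-1 in seeds, and 1 to 8 lists for seeds labelled heso1-4. In flowers it gave 1 to 2 genes up and 0 to 12 lists in urt1-1, 1 to 2 genes down and 5 to 8 lists in libraries labelled heso1-4 urt1-1, and 2 to 5 genes for these against libraries labelled heso1-4. Differences between tissues ranged from 0 to 1 for urt1-1 and from 1 to 2 for libraries labelled heso1-4. List medians that changed sign ranged from −0.412 to 0.046 for seed storage in urt1-1 seeds, from −0.213 to 0.038 for plastid-encoded genes in seeds labelled heso1-4 urt1-1, and in flowers from −0.234 to 0.032, −0.020 to 0.197 and −0.215 to 0.017 for plastid-encoded genes in urt1-1 and libraries labelled heso1-4 and heso1-4 urt1-1, from −0.111 to 1.362 for seed coat in urt1-1 and from −0.081 to 0.159 for ribosomal proteins in libraries labelled heso1-4 urt1-1. The libraries behind each are named beside the results.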

Other observations

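The 2 classes of genes described below, small nucleolar and small nuclear RNA genes, were among several tested after the data were seen. Camera called others too, such as non-coding RNA genes in seeds labelled heso1-4 (median 0.116, adjusted p = 0.0034, and 0.21 with an estimated correlation). Long non-coding RNA genes were called in urt1-1 seeds (−0.111, 0.034, and 0.29) and seeds labelled heso1-4 urt1-1 (−0.153, 0.0059, and 0.13). In seeds labelled heso1-4, the medians of 185 small nucleolar RNA genes and 37 small nuclear RNA genes stood at 0.49 and 0.61 against WT (camera adjusted p = 1.0e-11 and 0.00012), a difference lost with adjusted p = 0.21 and 0.29 with an estimated correlation. Replicate 3 of that group stood apart in composition, with 42.9% of its counts on its 10 top genes against 24.7% and 28.5% in replicates 1 and 2. The medians of these classes were not computed without that library. In urt1-1 seeds the 2 classes stood at −0.19 and −0.27 (0.0021 and 0.013, and 0.43 each with an estimated correlation), and in seeds labelled heso1-4 urt1-1 at −0.31 and −0.22 (2.6e-06 and 0.013, and 0.26 and 0.46 with an estimated correlation). In flowers labelled heso1-4 the 264 small nucleolar RNA genes tested stood at −0.20 (6.1e-06, and 0.58 with an estimated correlation) and the 42 small nuclear RNA genes at −0.22 (0.011, and 0.62). In flowers labelled heso1-4 urt1-1 the small nucleolar RNA genes stood at −0.17 (0.00048, and 0.73 with an estimated correlation). Not called by camera were the small nuclear RNA genes there (0.004, adjusted p = 0.78) and both classes in urt1-1 flowers (−0.071, 0.19 for small nucleolar and 0.032, 0.85 for small nuclear RNA genes). By edgeR, 0 genes of either class were called over all genes in any of these comparisons named here. Of all classes, 675, 1238, 1546, 623, 646 and 593 genes had an unadjusted p under 0.05 in the order given, and DESeq2 called 3 up and 0 down, 15 and 2, 55 and 19, 5 and 3, 15 and 0, and 5 and 1.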
